A study of Homo sapiens with 8 samples.

How the data were processed

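The 8 samples were total RNA of U2OS cells, 2 arrays for each of 4 groups taken from the treatment labels: untreated, CM354 (1.5 uM), doxorubicin (300 ng/ml) and doxorubicin plus CM354. Per the labels, RNA was isolated with TRIzol, treated with DNase, cleaned on columns, amplified and labelled with Cy3, and 1 sample was hybridised to each array. Per the file headers, the authors' scanner tables were made by Agilent Feature Extraction 10.7.3.1 with a one-colour protocol, with spatial and multiplicative detrending switched on and the separate global background adjustment off. The deposited scanner tables give each spot's signal as intensity on a linear scale, with no normalization between arrays. The other columns used of the deposited scanner tables are 0 or 1 marks for spots well above background, saturated or uneven. The values that the authors deposited in the series matrix are a ratio, each array's processed signal over the median of its noncontrol spots. Each matrix column had a median of 1 and differed from that ratio by less than 3e-05 of its value, so its scale and centring were found, and a one-colour signal has no direction to settle. The matrix was used only as an alternative.

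Of 42405 probes on the array, 26364 were named through their accession in the reference gene table, 2249 through a current symbol and 522 through a former symbol, and 13270 kept the name in the files. Probe coordinates are those of the files (GRCh37). The choices that follow, including gene lists and the rule for naming genes, were made before the data were examined unless stated otherwise. Control spots were left out, as were values of spots marked as outliers (228 to 334 spots per array), which left 28 probes without a complete set of values and out of the analysis. Each array's log2 processed signal was taken relative to the array's 75th percentile, and spots of one probe were averaged. A probe counted as well above background on an array when a share of at least 0.5 of its spots did, and it was kept when this held for both arrays of at least 1 group, which left 29492 probes. Each gene was represented by its kept probe with the highest mean signal. This gave 22833 genes, 16145 of them in the reference table and 6688 under the name in the files, and 5034 had several kept probes. Where probes of a named gene disagreed in sign or by over 1 (log2) in a comparison of 2 groups, the text gives their range. Interaction values come from the representing probe alone.

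Between 66.9% and 72.4% of spots lay well above background, median local background was 18.5 to 26 and median processed signal 110 to 121. With 2 arrays per group, the number of arrays limits the precision. A model with 4 group means was fitted to all 8 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 4 residual degrees of freedom, 1.59 prior degrees of freedom). Its 5 contrasts were CM354 versus untreated, doxorubicin versus untreated, both drugs versus untreated, both drugs versus doxorubicin, and the interaction. All tests were two-sided, with Benjamini-Hochberg adjustment within a contrast and a threshold of 0.05, and "called" means an adjusted p under it. Errors of log2 changes are standard errors from the model. The fitting was tested on simulated data: for doxorubicin versus untreated, 20.9%, 58.2% and 86.4% of changes of 0.5, 1 and 2 (log2) were recovered and 12 of 122 calls (9.84%) were false. For the interaction 0%, 29.9% and 69.7% were recovered, and 5 of 71 calls (7.04%) were false. Each simulation changed only 67, 67 and 66 of 22833 genes by these sizes, whereas 27.73% and 16.05% of genes were called in these contrasts of the data. The adjusted threshold depends on the share of changed genes, so these percentages are not the recovery in the data. Where a gene had no probe well above background on either array of a group, the text gives "at least N-fold", from the brighter group's mean over the mean, per array, of the higher of the probe's own signal and the lowest signal of any probe well above background on that array.

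The 27 gene lists were written from textbook knowledge: p53-activated targets, p53 arrest targets, p53 apoptosis targets, p53 pathway regulators, p53-linked noncoding RNAs, a panel of 9 genes (MDM2, CDKN1A, BAX, BBC3, GADD45A, FAS, CREBBP and EP300 among them), G2/M mitotic genes, G1/S and replication genes, replication-dependent histones, NF-kB inflammatory genes, interferon-stimulated genes, NRF2 targets, heat shock genes, endoplasmic reticulum and integrated stress genes, immediate early genes, CREB targets, acetylation genes, hypoxia genes, cholesterol and lipid synthesis genes, ribosomal proteins, ribosome biogenesis genes, matrix and TGF-beta genes, osteoblast markers, the BCL2 family with caspases, reference genes, leukocyte markers and epithelial markers. All 12 arrest and 17 apoptosis targets are also p53-activated targets, as are 6 of the 9 panel genes. The symbols H2AC11, AKR1C2, MIR34AHG, PANDAR and LYZ of these lists were not found among the probe names. Each list was tested against all other genes with limma's camera at a preset inter-gene correlation of 0.01, adjusted over 135 tests (27 lists by 5 contrasts). Of these 46 passed, and with the correlation estimated from the data 0 of 135 passed, so that value stands beside each of the 46 in the text. A list's relative median is its median log2 change minus that of all genes. Counts of members come from the gene tests, first over all genes tested and then over the list alone.

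Genes named in the text follow a rule. For each contrast they are the 10 highest and 10 lowest log2 changes among called genes in the reference table whose arrays did not overlap between groups (no such condition for the interaction), up to 4 members of each list with the smallest p, and the panel. The text may leave out genes of the first 2 kinds, and it describes 8 of the panel's 9 genes singly. The abundant leukocyte genes of the closing section come from a separate list.

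Slides were read from the array identifiers and numbered 1 to 3. Slide was a fixed block where a contrast could be estimated, a random block in all contrasts (consensus correlation 0.048), and slide 1 was also analysed alone. No paired analysis was possible because the labels do not pair samples across groups, and replicate numbers are only names. Other alternatives were quantile normalization, normexp background correction (offset 50) of mean signal and local background followed by quantile normalization or the 75th percentile, median scaling, no filter on dim probes, probes well above background on all arrays, the mean over a gene's probes, the series matrix, only the groups compared, an intensity trend with robust hyperparameters, array weights, a 2-fold minimum, which by construction ends every call under 2-fold, and leaving out each array in turn. A group left with 1 array is assumed to vary like the others. The list shifts were also tested with an estimated correlation and with fry, which asks whether a list's genes move one way on balance. Cyclic loess between arrays was added after seeing the data, as was the comparison of each list with 10000 random lists of genes matched on mean signal.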

Results

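Gene expression was measured in U2OS, a human osteosarcoma line, on 8 one-colour arrays. There were 2 arrays for each of 4 groups, which were untreated cells, cells given CM354 at 1.5 uM, cells given doxorubicin at 300 ng/ml, and cells given both. The series title calls CM354 a curcumin-based inhibitor of CBP, the acetyltransferase encoded by CREBBP, and doxorubicin is a DNA-damaging topoisomerase II poison. Each array held 58717 noncontrol spots, of which 66.9% to 72.4% lay well above background and 0 were saturated. Arrays of 1 group differed by a median of 0.098 to 0.126 (absolute log2 difference). In all, 22833 genes were tested, and the number of arrays limits the precision. The labels give no treatment time and do not say whether the 2 arrays of a group came from separate cultures. A gene's p-value therefore reflects only the spread between these samples, pooled over the 4 groups. A list's p-value instead sets its genes against all other genes and, at the preset correlation, takes them as nearly independent. Every gene called in the 4 comparisons of 2 groups had both arrays of one group beyond both arrays of the other. Chance alone would give this for 33.3% of genes picked without regard to their values. The called genes were picked by a small p on these same arrays, so the lack of overlap is no separate support.

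The 75th percentile of the signal was lower in every treated group, at 1385 and 1400 in the untreated arrays, 1183 and 1123 with CM354, 1276 and 1253 with doxorubicin, and 1009 and 1052 with both. The array medians lay between 110 and 121 in all groups. With the arrays scaled to their 75th percentile, the median log2 change of all genes was 0.15 with CM354, 0.15 with doxorubicin and 0.26 with both. Scaling to the array median instead moved these values by -0.27, -0.20 and -0.42. How many genes were higher or lower therefore depended on the scaling, and shifts of gene groups are given relative to the median of all genes. None of the 46 group shifts that passed their test changed sign under 5 other scalings. Median scaling, 1 of these 5, moves all genes of a contrast equally and cannot change such a shift. The untreated and doxorubicin arrays and CM354 replicate 2 shared slide 1, CM354 replicate 1 lay on slide 2, and both combined-treatment arrays lay on slide 3. Every comparison that uses the combined treatment is therefore also a comparison between slides.

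The first question is how cells given CM354 alone differed from untreated cells. The labels name no group given solvent alone, so a drug cannot be told apart from its solvent in any comparison with untreated cells. Genes of cell division and DNA replication fell together, as did genes of protein folding and ribosome production, while many p53 targets and several inflammatory genes rose. Of 51 mitotic genes 50 fell, and 50 adjusted over the list alone (relative median -0.96, adjusted p = 8.18e-27, and adjusted p = 0.42 with an estimated correlation). CCNA2, the cyclin of S phase and mitotic entry, fell 2.47-fold (log2 change -1.30 ± 0.07 SE, 2 arrays per group, adjusted p = 0.000627). The centromere histone chaperone HJURP and the cytokinesis protein ANLN changed by -0.99 and -1.14 (log2). Of 54 G1/S and replication genes 50 fell, and 53 adjusted over the list alone (relative median -0.81, adjusted p = 4.88e-24, and adjusted p = 0.445 with an estimated correlation). Among them were the phosphatase CDC25A at -1.10 and the flap endonuclease FEN1 at -0.81. Of 25 replication-dependent histone genes 21 fell and 1 rose, or 23 and 1 adjusted over the list alone (relative median -0.81, adjusted p = 1.53e-10, and adjusted p = 0.543 with an estimated correlation). H4C3 fell 2.56-fold, although histone genes are close copies and their probes do not separate them with certainty.

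Among 72 measured p53-activated targets 42 rose and 5 fell with CM354, or 44 and 5 adjusted over the list alone (relative median 0.25, adjusted p = 0.000104, and adjusted p = 0.167 with an estimated correlation). Counts of members depend on the scaling, since median scaling moves every log2 change in this contrast by -0.27. The arachidonate lipoxygenase ALOX5 rose 4.60-fold (log2 change 2.20 ± 0.10 SE, adjusted p = 0.000546), and the stress gene TP53INP1, the calcium channel subunit ORAI3 and the RNA-binding protein ZMAT3 rose by 1.41, 1.31 and 0.94. The cell-cycle inhibitor CDKN1A (chromosome 6, probe at 36652178 to 36652237, GRCh37) rose 1.46-fold (log2 change 0.55 ± 0.08 SE, adjusted p = 0.00514). The apoptosis gene BBC3 and the ubiquitin ligase gene MDM2 rose by 0.58 and 0.48 and the death receptor gene FAS by 0.44, whereas GADD45A fell by 0.31. BAX at 0.30, CREBBP at -0.21 and EP300, the paralog of CREBBP, at 0.20 did not pass. The 15 apoptosis targets (8 rose, 1 fell, adjusted p = 0.0791), the 12 arrest targets (4 rose, 2 fell, adjusted p = 0.719) and the 9 genes of the p53 panel (5 rose, 1 fell, adjusted p = 0.232) did not pass as groups, with the same counts adjusted over the list alone. Under median scaling CDKN1A, MDM2 and FAS lost their calls (0.28, 0.21 and 0.17) and CREBBP gained one (-0.48), and BAX gained one in 5 alternatives, 1 of them without untreated replicate 1 (0.45). Several alternatives ended the calls of GADD45A and FAS, among them leaving out untreated replicate 2 (-0.26 and 0.34), CM354 replicate 1 (-0.32 and 0.43) or CM354 replicate 2 (-0.29 and 0.45). Slide as a block and slide 1 alone also ended both calls (-0.32 and 0.43), and slide 1 alone that of MDM2 (0.43).

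Among the inflammatory, matrix, stress and ribosome biogenesis lists, some rose and others fell with CM354. Of 22 NF-kB and inflammatory genes 12 rose and 1 fell, or 12 and 2 adjusted over the list alone (relative median 0.17, adjusted p = 0.0188, and adjusted p = 0.42 with an estimated correlation), a call lost with normexp and the 75th percentile (adjusted p = 0.0569). The monocyte chemokine CCL2 rose 9.69-fold, TNF 9.32-fold, the growth factor CSF2 8.56-fold and the NF-kB inhibitor TNFAIP3 2.51-fold. Of 26 matrix and TGF-beta genes 14 rose and 2 fell, with the same counts adjusted over the list alone (relative median 0.27, adjusted p = 0.00837, and adjusted p = 0.615 with an estimated correlation), among them COL1A2 at 1.71 and FN1 at 1.35. Of 17 heat shock genes 14 fell, and 16 adjusted over the list alone (relative median -0.89, adjusted p = 3.49e-10, and adjusted p = 0.445 with an estimated correlation). The chaperone HSPA1A, a near-identical copy of HSPA1B, fell 2.90-fold and the co-chaperone AHSA1 1.66-fold. Of 25 NRF2 targets 13 fell and 4 rose, the same adjusted over the list alone (relative median -0.48, adjusted p = 0.000939, and adjusted p = 0.467 with an estimated correlation), with the redox enzymes TXNRD1 at -1.46, SRXN1 at -1.16 and NQO1 at -0.91. Of 29 endoplasmic reticulum and integrated stress genes 14 fell and 4 rose, or 15 and 4 adjusted over the list alone (relative median -0.41, adjusted p = 0.000165, and adjusted p = 0.529 with an estimated correlation), including CEBPG at -0.85. Of 31 ribosome biogenesis genes 29 fell, and 29 adjusted over the list alone (relative median -0.66, adjusted p = 2.4e-13, and adjusted p = 0.237 with an estimated correlation), including the helicase DDX21 and the assembly factor RRS1, which fell by 0.69 and 0.80. Acetylation genes (5 rose and 10 fell of 33, or 6 and 10 adjusted over the list alone, adjusted p = 0.0938), lipid synthesis genes (9 rose of 25, or 8 adjusted over the list alone, adjusted p = 0.079), p53 regulators (5 rose and 4 fell of 21, the same adjusted over the list alone, adjusted p = 0.29) and leukocyte markers (5 rose of 11, or 6 adjusted over the list alone, adjusted p = 0.145) did not pass. The deacetylase gene HDAC4 rose by 0.76, a call lost under quantile normalization.

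In all, 9735 genes passed with CM354, 5759 higher and 3976 lower, and 1745 of them differed at least 2-fold. The membrane protein gene MS4A15 rose 50.8-fold (log2 change 5.67 ± 0.29 SE, adjusted p = 0.00062) and the lens crystallin gene CRYBB1 28.9-fold, with 1 untreated array well above background. The immune receptor gene HAVCR2, not well above background in untreated cells, rose at least 16.3-fold. The protease inhibitor gene SPINK6 fell 7.99-fold, the natriuretic peptide gene NPPB 6.66-fold, the transcriptional inhibitor gene ID3 6.47-fold, the smooth muscle actin gene ACTG2 5.97-fold and the vitamin D hydroxylase gene CYP24A1 5.44-fold, the last with 1 CM354 array well above background. With slide as a block, as on slide 1 alone, CM354 replicate 2 is the only CM354 array that carries the contrast. Both fits therefore share their medians by construction. With the block, the relative medians were 0.29 for p53 targets, -0.90 for mitotic, -0.74 for replication, -0.75 for histone, 0.22 for inflammatory, 0.36 for matrix, -0.84 for heat shock, -0.42 for NRF2, -0.36 for endoplasmic reticulum and -0.59 for ribosome biogenesis genes. The arrays of slide 1 alone gave the same medians, and all 10 groups passed in both fits, as did apoptosis targets (adjusted p = 0.0323 and 0.038, and 0.438 and 0.528 with an estimated correlation) and lipid synthesis genes (adjusted p = 0.0261 and 0.0215, and 0.654 and 0.678 with an estimated correlation). With an estimated correlation no group passed in either fit (lowest adjusted p = 0.124 and 0.195). The number of genes called in CM354 versus untreated was 5351 with slide as a block and also without CM354 replicate 1, 2992 on slide 1 alone and 6007 without untreated replicate 2. Median scaling turned the split to 2508 higher and 7046 lower, quantile normalization to 3921 and 4233.

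**Figure D1:**
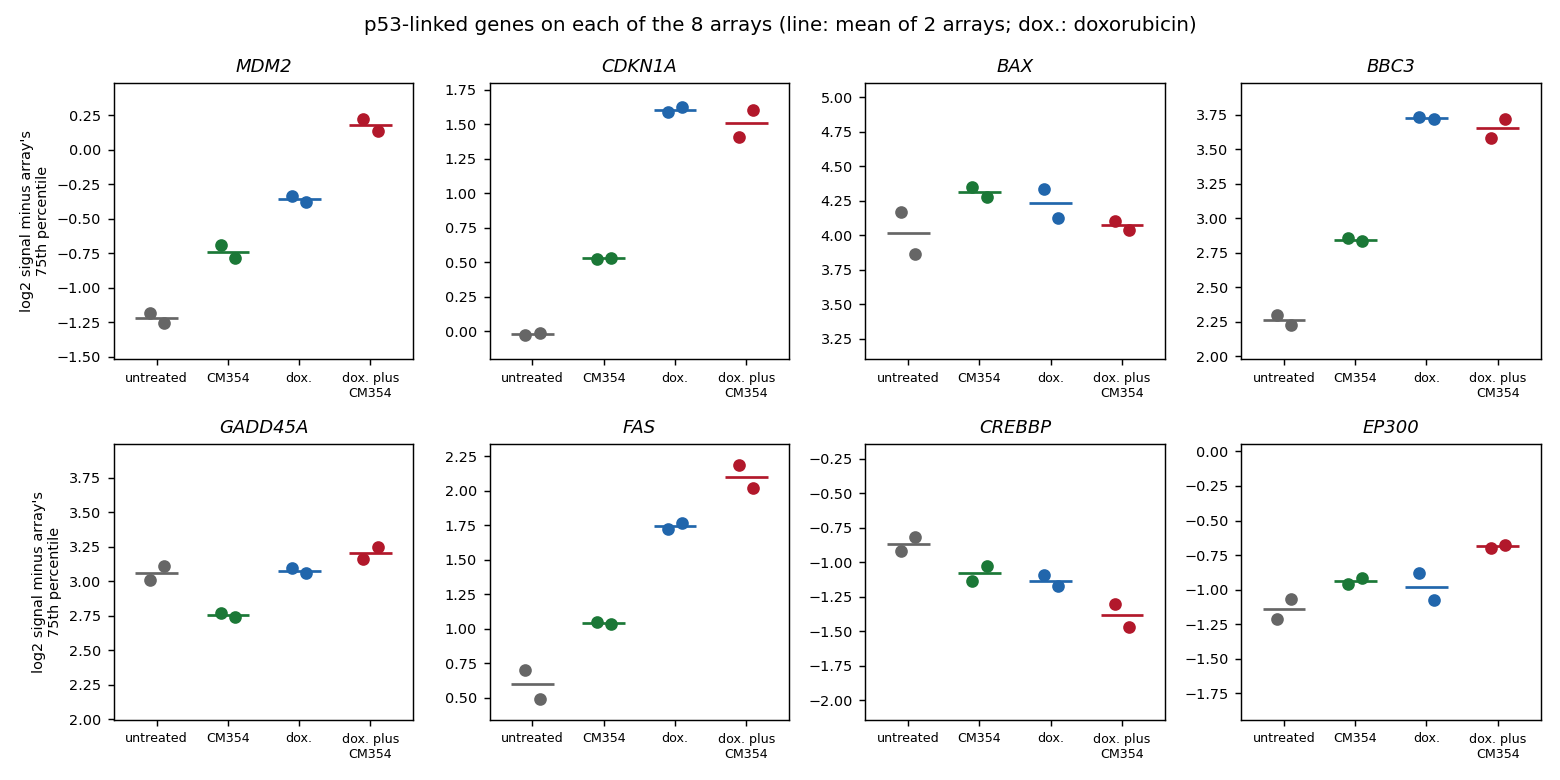
Each plot shows 1 of 8 genes of the p53 panel, with the 4 groups on the horizontal axis and the log2 signal minus the array's 75th percentile on the vertical axis. Points are the 8 arrays and lines the means of 2, which for CDKN1A were -0.02 untreated, 0.53 with CM354, 1.61 with doxorubicin and 1.51 with both, and for MDM2 were -1.22, -0.74, -0.36 and 0.18.

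The second question is how cells of the same line given doxorubicin alone differed from untreated cells. Doxorubicin raised p53 targets of both the arrest and the apoptosis kind and lowered mitotic genes, histone genes and ribosome biogenesis genes. Of the 72 p53-activated targets 57 rose and 3 fell, or 59 and 3 adjusted over the list alone (relative median 0.50, adjusted p = 2.05e-14, and adjusted p = 0.0636 with an estimated correlation). CDKN1A rose 3.09-fold (log2 change 1.63 ± 0.08 SE, 2 arrays per group, adjusted p = 0.000726), BBC3 2.76-fold (chromosome 19, probe at 47724174 to 47724233, GRCh37), FAS 2.22-fold and MDM2 1.81-fold. The growth factor gene PGF rose 7.25-fold and the death receptor gene TNFRSF10B 2.80-fold. Of 12 arrest targets 8 rose and 1 fell, the same adjusted over the list alone (relative median 0.72, adjusted p = 0.000604, and adjusted p = 0.445 with an estimated correlation), with the antiproliferative genes BTG2 and BTG1 at 1.86 and 1.48. Of 15 apoptosis targets 11 rose, and 12 adjusted over the list alone (relative median 0.44, adjusted p = 6.75e-05, and adjusted p = 0.226 with an estimated correlation). BAX at 0.22, GADD45A at 0.02, CREBBP at -0.27 (-0.47 and called under median scaling) and EP300 at 0.16 did not pass. The panel of 9 genes had 5 that rose, or 5 and 1 that fell adjusted over the list alone (relative median 0.61, adjusted p = 0.0291, and adjusted p = 0.42 with an estimated correlation).

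Of the 51 mitotic genes 44 fell with doxorubicin, and 47 adjusted over the list alone (relative median -0.94, adjusted p = 4.58e-32, and adjusted p = 0.38 with an estimated correlation). The mitotic kinase PLK1 fell 3.07-fold, the checkpoint kinase BUB1B 2.64-fold and the cyclin CCNF 3.23-fold. Of 25 histone genes 19 fell, and 22 adjusted over the list alone (relative median -0.65, adjusted p = 8.6e-14, and adjusted p = 0.491 with an estimated correlation), with the linker histone gene H1-4 at -1.38. The 54 G1/S and replication genes did not pass as a group (6 rose, 7 fell, or 3 and 5 adjusted over the list alone, relative median -0.17, adjusted p = 0.0714). They passed with slide as a block (adjusted p = 0.0497, and 0.836 with an estimated correlation) but not on slide 1 alone (adjusted p = 0.0561, and 0.523 with an estimated correlation). The sliding clamp gene PCNA rose by 0.75 and BRCA1 fell by 0.38, a call lost on the 4 arrays compared, without untreated replicate 2 (-0.35) and without doxorubicin replicate 2 (-0.34). Of 31 ribosome biogenesis genes 17 fell, and 22 adjusted over the list alone (relative median -0.48, adjusted p = 2.08e-12, and adjusted p = 0.238 with an estimated correlation). PPAN, RRS1 and the RNA polymerase I subunit gene POLR1B fell by 0.91, 0.99 and 0.92, and the transcription factor gene MYC fell 3.49-fold.

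Of 22 inflammatory genes 13 rose and 5 fell with doxorubicin, or 16 and 5 adjusted over the list alone (relative median 0.32, adjusted p = 0.0377, and adjusted p = 0.445 with an estimated correlation). The transcription factor gene IRF1 rose by 1.48, the NF-kB inhibitor gene NFKBIE by 1.11 and the cyclooxygenase gene PTGS2 by 1.08. Of 29 endoplasmic reticulum and integrated stress genes 7 fell and 6 rose, or 9 and 6 adjusted over the list alone (relative median -0.25, adjusted p = 0.0449, and adjusted p = 0.703 with an estimated correlation), and ATF3, a member that moved the other way, rose 3.07-fold. Of 25 cholesterol and lipid synthesis genes 5 fell and 2 rose, the same adjusted over the list alone (relative median -0.18, adjusted p = 0.0327, and adjusted p = 0.704 with an estimated correlation). The mevalonate kinase gene MVK fell by 0.62 and the squalene epoxidase gene SQLE by 0.69, the latter not called without untreated replicate 1 (-0.61) or doxorubicin replicate 2 (-0.68). Of 21 regulators of the p53 pathway 6 fell and 3 rose, or 8 and 3 adjusted over the list alone (relative median -0.26, adjusted p = 0.0103, and adjusted p = 0.499 with an estimated correlation). The acetyltransferase gene KAT5 fell by 0.85 and the checkpoint kinase gene CHEK2 by 0.70. Heat shock genes (1 rose and 1 fell of 17, the same adjusted over the list alone, adjusted p = 0.84), NRF2 targets (3 rose and 2 fell of 25, or 2 and 2 adjusted over the list alone, adjusted p = 0.799), acetylation genes (5 rose and 7 fell of 33, or 8 and 9 adjusted over the list alone, adjusted p = 0.125), matrix genes (7 fell of 26, the same adjusted over the list alone, adjusted p = 0.134) and leukocyte markers (5 rose and 1 fell of 11, the same adjusted over the list alone, adjusted p = 0.29) did not pass. HSPA6, an inducible chaperone gene, rose by 1.04, and DNAJB1 fell by 0.70. HDAC4 was -1.24 by its brightest probe and 0.59 by its other, so its direction is open.

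Doxorubicin changed 6332 genes, 3930 higher and 2402 lower, of which 1283 differed at least 2-fold. The homeobox gene OTP, not well above background in untreated cells, rose at least 21.2-fold. LRATD1 rose 17.2-fold (log2 change 4.11 ± 0.06 SE, adjusted p = 7.51e-05, with its 3 probes between 2.41 and 4.11), and the glutamate receptor subunit gene GRIN2C 9.85-fold (2 probes, 1.79 and 3.30). The keratin-associated gene KRTAP2-3 fell 11.5-fold, ZBED2 6.18-fold with 1 doxorubicin array well above background, the matrix gene ECM2 4.25-fold and the helicase gene PIF1 4.10-fold. All arrays of this comparison lie on slide 1, so neither a slide block nor slide 1 alone can change its log2 changes or medians. With slide as a block, or on the arrays of slide 1, the relative medians stayed as above and 10 and 9 of the 11 groups passed, the inflammatory group giving adjusted p = 0.0502 and adjusted p = 0.0778 and the panel adjusted p = 0.0394 and adjusted p = 0.0582. No group passed in either fit with an estimated correlation (adjusted p = 0.124 and 0.195 for p53 targets, 0.43 and 0.528 for the panel). The number of genes called in doxorubicin versus untreated was 3663 on the 4 arrays compared and 3857 with no filter on dim probes. It was 3651 without untreated replicate 1, 3051 without untreated replicate 2, 3567 without doxorubicin replicate 1 and 3359 without doxorubicin replicate 2. Median scaling turned the split to 1833 higher and 4229 lower. The inflammatory, endoplasmic reticulum, cholesterol, p53 regulator and panel calls held in 14, 15, 16, 21 and 20 of 23 alternatives. Leaving out untreated replicate 1 ended the endoplasmic reticulum and cholesterol calls (adjusted p = 0.127 and 0.171), and untreated replicate 2 the p53 regulator call (adjusted p = 0.0529). Leaving out doxorubicin replicate 1 ended the endoplasmic reticulum, cholesterol and panel calls (adjusted p = 0.122, 0.0669 and 0.0749), and doxorubicin replicate 2 the inflammatory and p53 regulator calls (adjusted p = 0.0926 and 0.0531). The inflammatory call also ended without either CM354 array (adjusted p = 0.0615 and 0.064) or either combined-treatment array (adjusted p = 0.0501 and 0.0523).

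Cells given both drugs were first set against untreated cells. Most p53 targets were higher with both drugs, nearly all mitotic, replication and histone genes were lower, and inflammatory genes included some of the largest rises. Of the 72 p53-activated targets 62 rose, and 63 adjusted over the list alone (relative median 0.67, adjusted p = 2.33e-10, and adjusted p = 0.0644 with an estimated correlation). The stress cytokine gene GDF15 rose 13.8-fold (log2 change 3.78 ± 0.13 SE, 2 arrays per group, adjusted p = 0.000139), PGF 5.53-fold (its 2 probes 2.47 and 3.52), ORAI3 4.13-fold and TNFRSF10B 3.58-fold. CDKN1A, FAS, MDM2 and BBC3 rose 2.88-fold, 2.84-fold, 2.63-fold and 2.62-fold, though the 4 probes of MDM2 ranged from 0.44 to 1.40 (log2). CREBBP fell 1.43-fold and EP300 rose 1.37-fold, the latter without a call under median scaling (log2 change 0.04). BAX at 0.06 and GADD45A at 0.14 did not pass, and GADD45A was -0.28 and called lower under median scaling. Of 12 arrest targets 10 rose, and 10 adjusted over the list alone (relative median 0.46, adjusted p = 0.00845, and adjusted p = 0.467 with an estimated correlation). Of 15 apoptosis targets 11 rose, and 11 adjusted over the list alone (relative median 0.79, adjusted p = 0.00817, and adjusted p = 0.38 with an estimated correlation).

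Of the 51 mitotic genes 50 fell with both drugs, and 50 adjusted over the list alone (relative median -1.43, adjusted p = 3.44e-29, and adjusted p = 0.409 with an estimated correlation). The centromere histone gene CENPA fell 6.06-fold, CCNA2 3.95-fold and HJURP 3.56-fold. Of 54 replication genes 48 fell and 1 rose, or 50 and 1 adjusted over the list alone (relative median -0.85, adjusted p = 1.47e-19, and adjusted p = 0.467 with an estimated correlation), with E2F2 and CCNE2 at -1.51 and -1.43. Of 25 histone genes 24 fell and 1 rose, the same adjusted over the list alone (relative median -1.22, adjusted p = 4.37e-13, and adjusted p = 0.499 with an estimated correlation), H4C3 4.55-fold. Of 17 heat shock genes 14 fell and 1 rose, the same adjusted over the list alone (relative median -0.89, adjusted p = 1e-06, and adjusted p = 0.467 with an estimated correlation). HSPA1A fell 2.98-fold, and HSPA6 rose 3.94-fold with its 3 probes between 1.98 and 3.06. Of 31 ribosome biogenesis genes 12 fell, and 12 adjusted over the list alone (relative median -0.38, adjusted p = 0.00102, and adjusted p = 0.467 with an estimated correlation), GNL3 and RRS1 by 0.58 and 0.49. The ribosome biogenesis call was lost in 2 of 21 alternatives.

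Of the 22 inflammatory genes 16 rose, or 16 with 1 that fell adjusted over the list alone (relative median 0.84, adjusted p = 0.000428, and adjusted p = 0.256 with an estimated correlation). CSF2 rose 28.4-fold, CCL2 8.46-fold, TNFAIP2 3.23-fold and the cytokine gene IL1A, not well above background in untreated cells, at least 16.3-fold. Of 33 acetylation genes 12 fell and 7 rose, or 11 and 7 adjusted over the list alone (relative median -0.34, adjusted p = 0.0113, and adjusted p = 0.467 with an estimated correlation). The acetyltransferase gene KAT7 fell by 0.85. HDAC7, a deacetylase gene, was -0.54 by its brightest probe and 0.57 by its other, so its direction is open. Of 11 leukocyte markers 9 rose, and 10 adjusted over the list alone (relative median 0.74, adjusted p = 0.00845, and adjusted p = 0.467 with an estimated correlation), CD68 6.50-fold, CD3D 4.31-fold and MS4A1 at least 4.35-fold. The acetylation call was lost with the mean over probes (adjusted p = 0.0947). The tumour suppressor gene CDKN2A rose 4.90-fold. NRF2 targets (8 rose and 10 fell, or 9 and 10 adjusted over the list alone, adjusted p = 0.11) did not pass. Nor did, with the same counts adjusted over the list alone, endoplasmic reticulum genes (4 rose and 9 fell, adjusted p = 0.0658), matrix genes (11 rose and 6 fell, adjusted p = 0.744), lipid synthesis genes (6 rose and 5 fell, adjusted p = 0.311), p53 regulators (8 rose and 7 fell, adjusted p = 0.352) and the panel (6 rose and 1 fell, adjusted p = 0.106).

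Both drugs together changed 14465 genes, 9947 higher and 4518 lower, and 5655 differed at least 2-fold. MYH16 rose 41.3-fold (log2 change 5.37 ± 0.27 SE, adjusted p = 0.000195), the collagenase gene MMP1 31.4-fold and the noncoding RNA LINC00520 19.1-fold. MYCT1 and the endothelial gene ESM1, not well above background in untreated cells, rose at least 30.7-fold and at least 21.9-fold. SPINK6 fell 9.59-fold with 1 combined-treatment array well above background, ECM2 8.73-fold (2 probes, -3.13 and -2.00), ACTG2 8.61-fold, SHISA3 7.82-fold and NPPB 7.61-fold. Neither slide as a block nor slide 1 alone could give this comparison, so slide and treatment cannot be told apart. Median scaling turned the split to 5317 higher and 9087 lower.

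The next comparison asks what CM354 added in cells that already received doxorubicin. The p53 targets did not pass as a group against all other genes, while replication, mitotic, histone and heat shock genes were lower with both drugs than with doxorubicin alone and inflammatory genes higher. Of 72 p53 targets 30 rose and 9 fell, or 31 and 9 adjusted over the list alone (relative median 0.0004, adjusted p = 0.474, and adjusted p = 0.615 with an estimated correlation). Against random lists matched on mean signal, compared after seeing the data, their median of 0.15 lay at percentile 98.3 (random lists 0.01). Whether they shifted therefore depends on the genes they are set against. The cytokine gene LIF rose 2.30-fold and ORAI3 1.91-fold, whereas the apoptosis gene CDIP1 fell 1.57-fold and the phosphatase gene PPM1D 1.50-fold. CDKN1A changed by -0.10 ± 0.08 SE (log2, 2 arrays per group, adjusted p = 0.34), BBC3 by -0.07 (adjusted p = 0.43), BAX by -0.16, GADD45A by 0.13 and CREBBP by -0.25, none of which passed. Under median scaling CDKN1A, BBC3 and CREBBP were called at -0.32, -0.29 and -0.47, and CREBBP in 9 alternatives in all. FAS rose by 0.36 and EP300 by 0.29, calls lost under the 2-fold minimum and in 8 and 15 other alternatives, median scaling among them (0.14 and 0.07). FAS was not called without either CM354 array (0.36), doxorubicin replicate 1 (0.34) or 2 (0.38) or combined-treatment replicate 1 (0.27), and EP300 kept its call only when the array left out was doxorubicin replicate 1 (0.19 to 0.30 without the others). MDM2 rose by 0.54 by its brightest probe, but its 4 probes ranged from -0.30 to 0.54 and their mean gave 0.15 (adjusted p = 0.16). Arrest targets (2 rose and 3 fell, or 2 and 2 adjusted over the list alone, adjusted p = 0.427), apoptosis targets (7 rose and 2 fell, the same adjusted over the list alone, adjusted p = 0.762) and the panel (3 rose, or 1 adjusted over the list alone, adjusted p = 0.874) did not pass.

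Of 54 replication genes 48 fell when CM354 was added to doxorubicin, and 50 adjusted over the list alone (relative median -0.70, adjusted p = 2.1e-20, and adjusted p = 0.467 with an estimated correlation). The cell-cycle transcription factor genes E2F2 and E2F1 fell 2.95-fold and 2.40-fold. Of 51 mitotic genes 38 fell, and 39 adjusted over the list alone (relative median -0.60, adjusted p = 2.4e-13, and adjusted p = 0.467 with an estimated correlation), CENPA 2.23-fold and the regulator FOXM1 2.11-fold. Of 25 histone genes 16 fell and 2 rose, or 17 and 2 adjusted over the list alone (relative median -0.57, adjusted p = 5.28e-06, and adjusted p = 0.615 with an estimated correlation), H4C3 3.23-fold. Of 17 heat shock genes 12 fell and 1 rose, or 13 and 1 adjusted over the list alone (relative median -0.71, adjusted p = 8.94e-07, and adjusted p = 0.467 with an estimated correlation). HSPA1A fell 3.20-fold while HSPA6 rose 1.92-fold (3 probes, 0.94 to 2.5). Of 25 NRF2 targets 11 fell and 5 rose, the same adjusted over the list alone (relative median -0.38, adjusted p = 0.0234, and adjusted p = 0.541 with an estimated correlation). NQO1 fell by 0.73, and the group passed in 16 of 21 alternatives.

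Of 22 inflammatory genes 14 rose, and 14 adjusted over the list alone (relative median 0.29, adjusted p = 0.00445, and adjusted p = 0.38 with an estimated correlation). CSF2 rose 39.4-fold (log2 change 5.30 ± 0.10 SE, adjusted p = 5.17e-05, chromosome 5, probe at 131411452 to 131411511, GRCh37), CCL2 11.3-fold and IL1A 7.93-fold, the last with 1 doxorubicin array well above background. Of 11 leukocyte markers 7 rose, and 7 adjusted over the list alone (relative median 0.58, adjusted p = 0.0103, and adjusted p = 0.467 with an estimated correlation), CD68 6.17-fold and CD3D 3.74-fold. Cyclic loess, chosen after seeing the data, ended that call (adjusted p = 0.0593). Of 31 ribosome biogenesis genes 15 rose, and 15 adjusted over the list alone (relative median 0.10, adjusted p = 0.0299, and adjusted p = 0.61 with an estimated correlation), with PPAN and MYBBP1A at 0.52 and 0.51. That call held in 13 of 21 alternatives and not under median scaling, where 5 rose and 1 fell (adjusted p = 0.418), nor without doxorubicin replicate 1 or 2 or combined-treatment replicate 2 (adjusted p = 0.0573, 0.0701 and 0.0724). Endoplasmic reticulum genes (6 rose and 9 fell, or 7 and 9 adjusted over the list alone, adjusted p = 0.308), acetylation genes (6 rose and 10 fell, the same adjusted over the list alone, adjusted p = 0.141), matrix genes (12 rose and 5 fell, or 12 and 7 adjusted over the list alone, adjusted p = 0.569), lipid synthesis genes (7 rose and 2 fell, the same adjusted over the list alone, adjusted p = 0.933) and p53 regulators (8 rose and 3 fell, or 9 and 3 adjusted over the list alone, adjusted p = 0.635) did not pass. HDAC4 rose by 0.99, a call lost with normexp and quantile normalization (0.17).

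Adding CM354 to doxorubicin changed 10797 genes, 6693 higher and 4104 lower, of which 2522 differed at least 2-fold. MYH16 rose 34.2-fold, MMP1 27.7-fold, LINC00520 22.5-fold and the defensin gene DEFB103B 18.9-fold. The receptor gene GPR65, not well above background with doxorubicin, rose at least 12.3-fold, and the lipoprotein receptor gene OLR1, not well above background with both drugs, was at least 10.6-fold higher with doxorubicin alone. ACTG2 fell 8.97-fold, SPINK6 8.88-fold with 1 combined-treatment array well above background, and NPPB 8.36-fold. The combined-treatment arrays had a slide of their own here too, and a slide difference in part cannot be told apart from the treatment. The number of genes called in doxorubicin plus CM354 versus doxorubicin was 6525 without combined-treatment replicate 1 and 6776 without doxorubicin replicate 2, and median scaling turned the split to 3648 higher and 6631 lower.

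The effects of CM354 without and with doxorubicin were set against each other gene by gene. They share no arrays, and their log2 changes gave Pearson r = 0.539 and Spearman rho = 0.579 across 22833 genes, which are not independent replicates. Of 5951 genes called in both, 3272 were higher in both, 2129 lower in both and 550 moved in opposite directions. Independence of the calls would give 1688 higher and 715 lower in both. That baseline leaves out any trend on signal level that the comparisons share. Random lists matched on signal to the leukocyte markers had medians of 0.32 without and 0.40 with doxorubicin. ACTG2, NPPB and SPINK6 were lower and CSF2 and CCL2 higher in both comparisons.

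**Figure D2:**
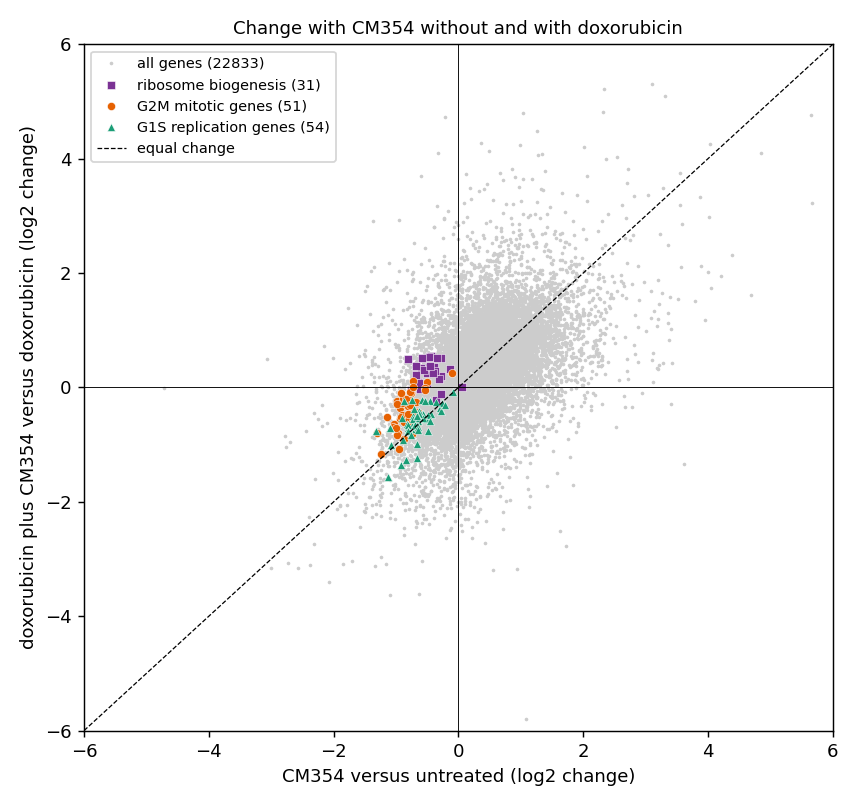
Each point is 1 of 22833 genes, with its log2 change with CM354 versus untreated on the horizontal axis and with doxorubicin plus CM354 versus doxorubicin on the vertical axis, and the dashed line marks equal change. Of 51 mitotic genes 50 fell on the horizontal axis and 38 on the vertical, while of 31 ribosome biogenesis genes 29 fell on the horizontal axis and 15 rose on the vertical, 5 under median scaling.

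The interaction asks whether the effect of both drugs differed from the sum of the single effects on the log2 scale, a positive value meaning more than the sum. Ribosome biogenesis genes had the highest relative median of the passing groups. It was -0.66 with CM354, -0.48 with doxorubicin and -0.38 with both, each against untreated cells. Of these 31 genes 26 had a higher value than the sum, and 28 adjusted over the list alone (relative median 0.72, adjusted p = 4.53e-15, and adjusted p = 0.226 with an estimated correlation). RRS1 gave 1.30 ± 0.11 SE (log2, adjusted p = 0.00538), PPAN 1.11 and the nucleolar gene NOP16 1.05. Of 51 mitotic genes 19 were above the sum, and 27 adjusted over the list alone (relative median 0.38, adjusted p = 1.23e-09, and adjusted p = 0.543 with an estimated correlation), BUB1B at 0.84 and PLK1 at 0.83. Of 29 endoplasmic reticulum and integrated stress genes 10 were above and 1 below, the same adjusted over the list alone (relative median 0.16, adjusted p = 0.0392, and adjusted p = 0.697 with an estimated correlation), TRIB3 at 0.96 and the transporter gene SLC3A2 at 0.85, a call lost without combined-treatment replicate 1 (0.80) or doxorubicin replicate 2 (0.86). Of 21 p53 regulators 2 were above, and 2 adjusted over the list alone (relative median 0.16, adjusted p = 0.0442, and adjusted p = 0.606 with an estimated correlation). These 2 were KAT5 at 0.67 and the checkpoint kinase gene ATR at 0.56, the latter not called when any 1 array but doxorubicin replicate 1 was left out (0.49 to 0.58, adjusted p = 0.0609 to 0.0715).

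The p53-activated targets as a group were below the sum of the single effects. Of 72 targets 18 were below and 6 above, or 32 and 6 adjusted over the list alone (relative median -0.33, adjusted p = 2.9e-05, and adjusted p = 0.167 with an estimated correlation). ALOX5 gave -1.46, TP53INP1 -1.04 and BTG2 -0.97, while the repressor gene PRDM1 gave 1.68. CDKN1A gave -0.65 ± 0.11 SE (log2, adjusted p = 0.0211) and BBC3 -0.65 (adjusted p = 0.0152), both under 2-fold. CDKN1A was not called when any 1 untreated, CM354 or doxorubicin array was left out (-0.63 to -0.67, adjusted p = 0.0597 to 0.0741), nor BBC3 without CM354 replicate 1, untreated replicate 2 or either doxorubicin array (-0.62 to -0.66, adjusted p = 0.0506 to 0.0582). GADD45A gave 0.43 (adjusted p = 0.0371), and lost its call when any 1 of the 8 arrays was left out (0.38 to 0.48, adjusted p = 0.0617 to 0.116). MDM2 at 0.06, BAX at -0.46, FAS at -0.09, CREBBP at -0.04 and EP300 at 0.09 did not pass. The value of MDM2 is that of its brightest probe. Its 4 probes ranged from 0.29 to 0.48 with CM354 and from -0.30 to 0.54 with both against doxorubicin. Of 15 apoptosis targets 3 were below, and 4 adjusted over the list alone (relative median -0.32, adjusted p = 0.0304, and adjusted p = 0.42 with an estimated correlation). Arrest targets (3 above and 4 below, or 3 and 6 adjusted over the list alone, adjusted p = 0.145) and the panel (1 above and 2 below, the same adjusted over the list alone, adjusted p = 0.342) did not pass.

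The other groups did not pass in the interaction. These were inflammatory genes (6 above and 4 below, or 7 and 4 adjusted over the list alone, adjusted p = 0.475), matrix genes (4 and 9, or 5 and 11 adjusted over the list alone, adjusted p = 0.186), leukocyte markers (4 and 0, the same adjusted over the list alone, adjusted p = 0.125), NRF2 targets (5 and 2, or 7 and 2 adjusted over the list alone, adjusted p = 0.178) and acetylation genes (5 and 1, or 5 and 2 adjusted over the list alone, adjusted p = 0.928). Further ones were lipid synthesis genes (1 and 5, or 1 and 6 adjusted over the list alone, adjusted p = 0.153), heat shock genes (2 and 1, the same adjusted over the list alone, adjusted p = 0.124), histone genes (3 and 1, the same adjusted over the list alone, adjusted p = 0.134) and replication genes (2 and 1, or 0 and 0 adjusted over the list alone, adjusted p = 0.329). Within these groups CSF2 gave 2.20, CD68 2.02, CD3D 1.49, TNF -2.82 and the collagen gene COL1A1 -1.18.

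The interaction passed for 3665 genes, 1787 above the sum and 1878 below it, of which 1044 reached 2-fold. The cornified envelope gene SPRR2A gave 4.30 ± 0.45 SE (log2, adjusted p = 0.00725), MMP1 3.77 and the stromelysin gene MMP3 3.47, while SHISA2 gave -3.13, SECTM1 -3.01 and UBE2QL1 -2.85. MYC gave 1.68 and HSPA6 1.75, while FOS and EGR2, both immediate early genes, gave -1.91 and -2.45. Slide and combined treatment cannot be told apart in this contrast. The number of genes called in the interaction of doxorubicin and CM354 was 1425 with no filter on dim probes. It was 1925 and 1647 without untreated replicate 1 or 2, 1780 and 1987 without CM354 replicate 1 or 2, 1935 and 1246 without doxorubicin replicate 1 or 2, and 1592 and 1639 without combined-treatment replicate 1 or 2. The apoptosis target, endoplasmic reticulum and p53 regulator calls held in 16, 14 and 10 of 20 alternatives. Apoptosis targets did not pass without doxorubicin replicate 1, untreated replicate 2 or combined-treatment replicate 2 (adjusted p = 0.0589 to 0.0767). Endoplasmic reticulum genes did not without untreated replicate 1, CM354 replicate 1, doxorubicin replicate 1 or either combined-treatment array (adjusted p = 0.0505 to 0.131). The p53 regulators did not without replicate 2 of any group (adjusted p = 0.0685 to 0.151).

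**Figure D3:**
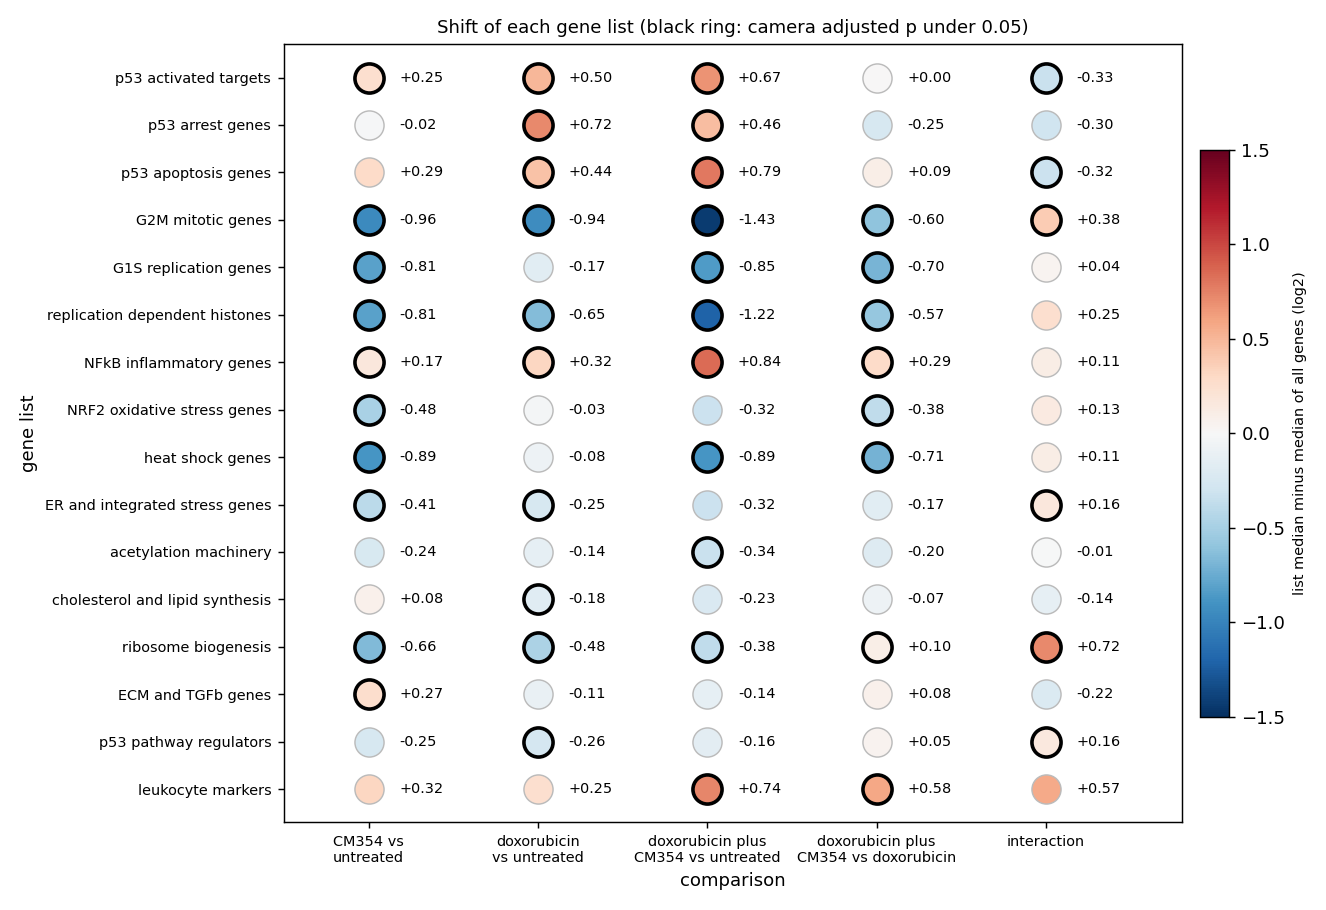
Each row is a gene list and each column a comparison. The colour and the printed number give the list's median log2 change minus that of all genes, and a black ring marks an adjusted p under 0.05 with the preset correlation. Mitotic genes were at -0.96, -0.94, -1.43 and -0.60 in the 4 comparisons of 2 groups, and ribosome biogenesis genes at 0.72 in the interaction. No ringed value changed sign under 5 other scalings, of which median scaling cannot change it by construction.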

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

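Among the tests below, those of signal-dependent compression and of probe GC content as the whole cause of the changes, and that of leukocyte RNA by the abundant transcripts it would bring, were chosen only after the result was seen. The change with CM354 differed between arrays with and without doxorubicin for 3665 genes, by the test of the interaction itself. Slide and combined treatment cannot be told apart in this test. The same test gave a median interaction (log2) of -0.3155 for p53-activated targets, -0.3069 for p53 apoptosis targets, 0.3964 for mitotic genes, 0.182 for endoplasmic reticulum and integrated stress genes, 0.7389 for ribosome biogenesis genes and 0.1766 for p53 pathway regulators. With an estimated correlation none of these 6 groups passed (adjusted p = 0.167, 0.42, 0.543, 0.697, 0.226 and 0.606). BAX and MDM2 did not pass in the interaction, which does not show that they were equal.

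The first pattern is the set of 10797 genes, CSF2 and CENPA among them, that changed when CM354 was added to doxorubicin, where the combined-treatment arrays had a slide of their own. A slide or scan difference as the whole cause is argued against, because 80.35% and 80.76% of these genes moved the same way in CM354 replicate 2 against the untreated arrays of its slide, where independence would give 52.0% and 52.4%. Removing the trend of the change on signal left 73.51% of the calls with their direction, and removing the trend on probe GC content left 72.06%, which argues against either trend as the whole cause. Each trend may still account for a part, since both values fell between the bounds set for the test, and a slide difference in part cannot be told apart from the treatment. A response to CM354 stays open as the biological explanation and was not tested further.

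The second pattern is the interaction of ribosome biogenesis genes, RRS1 and PPAN among them. Their signal level as the cause is argued against, because the median interaction lay at percentile 100 of 10000 random lists matched on mean signal. The median of these genes against the untreated mean was also taken relative to that of all genes on each array. It was -0.70 and -0.59 on the CM354 arrays, -0.45 and -0.47 on the doxorubicin arrays and -0.41 and -0.35 on the combined-treatment arrays. A slide or scan difference cannot be told apart from the combined treatment, since 0 slides held combined-treatment arrays beside another group. An effect of both drugs that is less than the sum of the single effects may be the biological explanation, and it stays open as untested.

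The third pattern is the rise of leukocyte markers, CD68 and CD3D among them, with both drugs in a cultured osteosarcoma line. Leukocyte RNA stays open as a candidate explanation, because the test with bounds set beforehand was undecided: 36.84% of 19 abundant leukocyte genes, 7 in all, were well above background on both combined-treatment arrays and had risen by at least the median of the markers. Of the 13 well above background 10 rose, among them CD53 by 3.17, LAPTM5 by 2.69, SRGN by 2.31, AIF1 by 2.13, LCP1 by 1.74 and HCLS1 by 1.50, while ITGB2 fell by 0.55, and the other 6 (CD37, CD52, CD74, HLA-DRA, S100A8 and S100A9) lie near the floor, so that leukocyte RNA, judged by the abundant transcripts it would bring, is neither excluded nor shown. A rise that dim probes share stays open too, since the markers' median lay at percentile 76.21 of random lists matched on signal. A change in the cells themselves is also open and was not tested, and 10 of the 11 markers were already well above background on an untreated array.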

How the results depend on the processing

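Cyclic loess was chosen only after the result was seen. The genes called in CM354 versus untreated went from 9735 to 5351 with slide as a fixed block, 2992 on the arrays of slide 1 alone and 1745 with a 2-fold minimum. Those counted as genes called in doxorubicin versus untreated went from 6332 to 3857 with no filter on dim probes, 3663 on the arrays compared, 3663 on slide 1 alone and 1283 with a 2-fold minimum. That minimum left 5655 genes called in doxorubicin plus CM354 versus untreated and 2522 genes called in doxorubicin plus CM354 versus doxorubicin. It left 1044 genes called in the interaction of doxorubicin and CM354, and no filter on dim probes left 1425. The minimum and the smaller sets of arrays lower a count by construction, and for the filter the cause was not tested. Leaving out each array in turn gave 5351 to 9083, 3051 to 5760, 10924 to 14033, 6525 to 10343 and 1246 to 1987 genes in these 5 contrasts. The other alternatives gave counts within 1.5 times the reported ones.

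The p53 target list shift in doxorubicin versus untreated was 0.4978 and did not pass with an estimated correlation (adjusted p = 0.0636, range over its alternatives 3e-52 to 0.0636), and leaving out an array gave 0.4945 to 0.578. The p53 target list shift in doxorubicin plus CM354 versus doxorubicin was 0.0004 and passed only with fry (adjusted p = 0.000109, range over its alternatives 0.000109 to 0.846), which asks whether the targets move one way and not whether they differ from other genes. Leaving out an array gave -0.0555 to 0.0047. GADD45A log2 change in doxorubicin plus CM354 versus untreated was -0.277 under median scaling and in the series matrix (adjusted p = 0.0217, range over its alternatives 0.0217 to 0.372), a scaling that lowers every change in this contrast by the same amount. HDAC7 log2 change in doxorubicin plus CM354 versus untreated was 0.015 with the mean over probes (adjusted p = 0.928, range over its alternatives 3.6e-05 to 0.928), because its 2 probes differ in sign.

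Over the 244 values of named genes, 5333 of 5515 alternative values kept their direction and side of the threshold, 153 lost a call, 26 gained one and 3 changed sign. Of those that lost a call, 58 did so by the 2-fold minimum and 49 by leaving out 1 array. Apart from the panel, the named genes were picked for large changes or small p on these same arrays. The share that kept a call is therefore no measure for the called genes as a whole. Median scaling and the series matrix hold the same scaling and are counted separately. The fixed slide block and slide 1 alone could not be estimated for the contrasts with the combined treatment, and the interaction uses all groups. Signal over background limits the dim genes, since 66.9% to 72.4% of spots lay well above it.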

Other observations

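The comparison of lists with random lists matched on signal, given last, was chosen only after the result was seen. Immediate early genes moved in both directions and did not pass as a group. Of 26, 15 rose and 7 fell with CM354 (16 and 7 adjusted over the list alone, adjusted p = 0.167), 11 and 10 with doxorubicin (the same adjusted over the list alone, adjusted p = 0.401), and 18 and 6 with both (the same adjusted over the list alone, adjusted p = 0.427). When CM354 was added to doxorubicin 12 rose and 7 fell (13 and 8 adjusted over the list alone, adjusted p = 0.405), and 7 and 7 passed in the interaction (9 and 11 adjusted over the list alone, adjusted p = 0.637). EGR2 rose 5.98-fold, FOS 3.20-fold and EGR1 2.38-fold with CM354, whereas KLF2 fell 2.30-fold. With both drugs JUNB and FOS rose by 1.32 and 1.40 (log2), while the phosphatase gene DUSP1 fell by 1.68. KLF6 was 1.20 by its brightest probe when CM354 was added to doxorubicin, but its 3 probes ranged from -0.80 to 1.20. Of 14 CREB targets 4 rose and 6 fell with CM354 (5 and 6 adjusted over the list alone, adjusted p = 0.45), 6 and 3 with doxorubicin (the same adjusted over the list alone, adjusted p = 0.719), 11 and 1 with both (12 and 1 adjusted over the list alone, adjusted p = 0.0714), 7 and 4 with both against doxorubicin (8 and 5 adjusted over the list alone, adjusted p = 0.689) and 4 and 1 in the interaction (the same adjusted over the list alone, adjusted p = 0.305). The nuclear receptor gene NR4A2 rose by 1.51 with doxorubicin and 1.74 with both, and the growth factor gene AREG gave 1.54 in the interaction.

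Regulators of apoptosis and noncoding RNAs linked to p53 also had members with large changes. Of 24 BCL2 family and caspase genes 5 rose and 7 fell with CM354 (6 and 8 adjusted over the list alone, adjusted p = 0.29), 5 and 5 with doxorubicin (6 and 6 adjusted over the list alone, adjusted p = 0.651), 4 and 8 with both (the same adjusted over the list alone, adjusted p = 0.109), 3 and 9 with both against doxorubicin (the same adjusted over the list alone, adjusted p = 0.161) and 1 and 4 in the interaction (5 and 5 adjusted over the list alone, adjusted p = 0.757). The proapoptotic gene BMF and the caspase gene CASP10 rose by 1.91 and 1.16 with CM354 and gave -2.58 and -0.98 in the interaction. BIK, another proapoptotic gene, rose by 1.47 with doxorubicin, and the antiapoptotic gene BCL2L1 by 0.97 with both and by 0.93 with both against doxorubicin. Of 10 noncoding RNAs 5 rose with CM354 (6 adjusted over the list alone, adjusted p = 0.175), 2 with doxorubicin (3 adjusted over the list alone, adjusted p = 0.29), and 6 rose and 1 fell with both (the same adjusted over the list alone, adjusted p = 0.397). With both against doxorubicin 3 rose and 1 fell (the same adjusted over the list alone, adjusted p = 0.992), and 3 were below the sum in the interaction (the same adjusted over the list alone, adjusted p = 0.186). By its brightest probe PURPL rose 4.92-fold with CM354, 4.18-fold with doxorubicin (its 2 probes 0.04 and 2.06) and 3.41-fold with both, and gave -2.59 in the interaction. Its other probe gave 2.03, 0.04 and 2.45 (log2) in these comparisons with untreated cells. That probe was not below the sum of the single effects, so the direction of the interaction is open.

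Of 22 interferon-stimulated genes 8 rose and 4 fell with CM354 (10 and 4 adjusted over the list alone, adjusted p = 0.362), 8 and 2 with doxorubicin (10 and 2 adjusted over the list alone, adjusted p = 0.244), 13 and 5 with both (the same adjusted over the list alone, adjusted p = 0.37), 8 and 6 with both against doxorubicin (9 and 6 adjusted over the list alone, adjusted p = 0.83) and 0 and 4 in the interaction (the same adjusted over the list alone, adjusted p = 0.194). OASL rose 3.99-fold with CM354, 2.49-fold with doxorubicin, 6.48-fold with both and 2.60-fold with both against doxorubicin, the RNA sensor gene RIGI rose by 1.03 (log2) with CM354, and IFIT1 fell by 1.42 with both. Of 28 hypoxia genes 9 rose and 9 fell with CM354 (10 and 11 adjusted over the list alone, adjusted p = 0.522), 5 and 3 with doxorubicin (9 and 6 adjusted over the list alone, adjusted p = 0.635), 13 and 6 with both (14 and 6 adjusted over the list alone, adjusted p = 0.933), 9 and 8 with both against doxorubicin (the same adjusted over the list alone, adjusted p = 0.557) and 3 and 5 in the interaction (5 and 7 adjusted over the list alone, adjusted p = 0.569). The glucose transporter gene SLC2A3 rose by 1.23 with CM354, 1.08 with both and 1.68 with both against doxorubicin. With doxorubicin the prolyl hydroxylase gene EGLN3 rose by 1.95 and the hexokinase gene HK2 fell by 1.44, and HK2 rose by 1.20 when CM354 was added and gave 1.79 in the interaction.

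Of 11 osteoblast markers 5 rose and 3 fell with CM354 (5 and 4 adjusted over the list alone, adjusted p = 0.963), and, with the same counts adjusted over the list alone, 2 and 2 with doxorubicin (adjusted p = 0.633), 6 and 3 with both (adjusted p = 0.927), 6 and 4 with both against doxorubicin (adjusted p = 0.968) and 3 and 2 in the interaction (adjusted p = 0.933). RUNX2, a regulator of osteoblast differentiation, rose by 1.18 with CM354, BMP2 by 1.76 with doxorubicin, and SPP1 by 1.19 with both and 1.25 with both against doxorubicin. Of 8 epithelial markers 5 rose with CM354 (the same adjusted over the list alone, adjusted p = 0.0647; adjusted p = 0.0456 with slide as a block, or 0.602 with an estimated correlation, and 0.0582 on slide 1 alone), and 3 rose and 2 fell with doxorubicin (the same adjusted over the list alone, adjusted p = 0.871). The counts were 2 and 2 with both (the same adjusted over the list alone, adjusted p = 0.557), 2 and 1 with both against doxorubicin (the same adjusted over the list alone, adjusted p = 0.871) and 2 and 3 in the interaction (2 and 5 adjusted over the list alone, adjusted p = 0.183). KRT14 rose by 1.08 with CM354, KRT19 by 1.81 with both, and CDH1 fell by 0.89 with doxorubicin. Of 12 reference genes 2 rose and 4 fell with CM354 (the same adjusted over the list alone, adjusted p = 0.186), 1 rose with doxorubicin (the same adjusted over the list alone, adjusted p = 0.916), and 4 and 3 passed with both (the same adjusted over the list alone, adjusted p = 0.927), 2 and 3 with both against doxorubicin (4 and 5 adjusted over the list alone, adjusted p = 0.513) and 1 and 0 in the interaction (the same adjusted over the list alone, adjusted p = 0.399). The transferrin receptor gene TFRC rose by 1.08 with both and 1.30 with both against doxorubicin and gave 1.29 in the interaction, and HPRT1 fell by 0.45 with CM354, a call lost on slide 1 alone. Of 46 ribosomal protein genes 0 were called with CM354, with doxorubicin and in the interaction (0 adjusted over the list alone, adjusted p = 0.215, 0.181 and 0.134). With both drugs 10 rose (0 adjusted over the list alone, adjusted p = 0.412), among them RPS2 at 0.49, whose 4 probes ranged from -0.02 to 0.49 and whose call ended under the 2-fold minimum and 5 other alternatives, and with both against doxorubicin 1 rose and 1 fell (0 adjusted over the list alone, adjusted p = 0.77).

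Of the 46 list results that passed, 39 lay outside the central 95% of 10000 random lists matched on mean signal. The 7 inside it were inflammatory genes with CM354 (percentile 92.43), lipid synthesis genes with doxorubicin (12.76), acetylation genes (8.43), ribosome biogenesis genes (9.19) and leukocyte markers (76.05, from other random lists than those above) with both drugs, leukocyte markers with both against doxorubicin (90.4) and p53 regulators in the interaction (95.35). Of the 89 that did not pass, 15 lay outside it, p53 targets with both against doxorubicin among them (percentile 98.3, median 0.15 against 0.01 for the random lists).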
